A study of Salamandra salamandra with 23 samples.

How the data were processed

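RNA from tail clips of fire salamander larvae was hybridised in 1 colour (Cy3) to a custom Agilent array, 1 array per sample, at 4 stages of development. Per the labels' protocols, RNA was extracted with Trizol. Per the file headers, images were read with Feature Extraction 10.7.3.1 for array design 069636. The deposited processed signal of each spot is an intensity on a linear scale, background-subtracted and spatially detrended by that program per the file headers, with a surrogate value where a spot was not above background. The files also hold the mean signal and background median, likewise intensities, and flags for outlier spots, for saturation and for spots well above background. The authors' series matrix, as deposited, holds for each probe the ratio of linear signal to the array's 75th percentile, a normalization found here by comparison with the scanner values. How its zeros and missing values were set is not given in the sources used here. Their columns had medians between 0.1765 and 0.2579, and each column correlated best with its own array.

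Each array has 62976 spots. Of these, 61657 are no controls, and they hold 12486 distinct probe sequences of 60 bases in 4 to 15 spots each. Spots with an outlier flag were left out (630 to 1354 per array), and saturated spots were kept. The log2 processed signal minus the array's 75th percentile was averaged over the spots of each sequence. A probe was well above background on an array when at least 50% of its spots were, and it was tested when it was so on at least 5 arrays, the size of the smallest stage. This left 11635 probes. The median processed signal per array averaged 143.9 ± 16.0 in PreM (SD, n = 5), 195.5 ± 41.0 in early ProM (n = 5), 146.9 ± 26.7 in late ProM (n = 6) and 129.1 ± 32.2 in Meta (n = 7). Arrays lay on 3 slides, each scanned on its own, with 1 scan day for slide 1 and another for slides 2 and 3, so slide stands for scan as well. Slide 1 held 3 PreM, 1 early ProM, 2 late ProM and 2 Meta arrays, slide 2 held 2, 2, 3 and 1, and slide 3 held 0, 2, 1 and 4.

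Stages were taken from the labels. Stage means were fitted to all 23 arrays together with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without covariates, and the 6 pairs of stages were compared as later minus earlier, with Benjamini-Hochberg adjusted p under 0.05 within each. A moderated F test compared the 4 stages. Shares of variance were sums of squares over all tested probes. They were tested by exact permutation for pairs of stages, adjusted over the 6 pairs, and with 100000 permutations for all stages. The text names at most 2 probes higher and 2 lower per comparison, those with the largest log2 difference among probes past the threshold whose 2 stages did not overlap. This rule, the tests and most alternatives were fixed before the data were examined. Where a probe was not well above background on any array of a stage, its fold is a bound. The bright stage's mean was set against the mean of, per array, the higher of the probe's own level and the lowest level of any probe well above background. A bound rests on that lowest level and can exceed the difference after normexp correction. The adjusted p beside a bound is that of the fitted log2 difference.

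The fit was tested on simulated values for 11634 probes with 200 changed. It recovered 44% of 2-fold and 89% of 4-fold changes from PreM to early ProM, with 10 false calls, and 55% and 86% from early to late ProM, with 2. From late ProM to Meta it recovered 63% and 90%, with 8, and from PreM to Meta 55% and 91%, with 12. The simulated noise was independent between probes and between arrays, without slide effects. These counts of false calls therefore need not carry over to the real arrays, whose probes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

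Slides were also compared with each other, a test chosen after the data were seen. Probes at least 2-fold different on one slide were read on another, and the share expected if unrelated came from the shares of rises on each.

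Alternatives were normexp background correction (offset 50), quantile normalization, scaling to the median, no filter, a filter asking for all 23 arrays, the authors' values (zeros taken as missing, 11409 probes), slide as a fixed or random block, each slide alone, day as a covariate, only the stages compared, array weights, a 2-fold or a stricter threshold, a spread with an intensity trend, and leaving out each array. Added after the data were seen were the array's signal over its spike-in signal as a covariate (75th percentile minus the mean of 7 spike-in probes, log2), the same with a slide block, and averaging by probe name. Gene lists drawn up before the data were examined, among them thyroid hormone response, keratins, globins and immune markers, were not run, because the files used here do not pair contigs with gene names. Other probes of a named probe's gene were not compared for the same reason. Replicate numbers only name samples and pair none.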

Results

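Gene expression was measured in tail clips of fire salamander (Salamandra salamandra) larvae at 4 stages of postembryonic development. The stages were premetamorphosis (PreM, n = 5), early prometamorphosis (early ProM, n = 5), late prometamorphosis (late ProM, n = 6) and metamorphic climax (Meta, n = 7). Premetamorphosis is the phase of larval growth before visible change, prometamorphosis that of gradual change, and the climax that of the most rapid remodelling. Each of the 23 samples was hybridised to 1 array of a single colour (Cy3), and each carried its own identifier in the labels. The labels do not state outright that the samples came from separate animals, so p-values set differences against the spread between these samples. Mean age after larviposition, the release of larvae by the female, was 25.6 ± 10.8 days in PreM (SD, n = 5), 42.4 ± 7.3 days in early ProM (n = 5), 57.3 ± 7.4 days in late ProM (n = 6) and 53.1 ± 6.5 days in Meta (n = 7). Ages overlapped between neighbouring stages: PreM samples were 12 to 40 days old and early ProM samples 36 to 52 days, and both late ProM and Meta began at 44 days.

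The arrays carried 12486 distinct probe sequences of 60 bases, designed on contigs of an assembled transcriptome. Of these, 11635 were bright enough to be tested. The share of probes well above background was 87.3% ± 2.7 in PreM (SD, n = 5), 89.1% ± 2.9 in early ProM (n = 5), 87.5% ± 1.9 in late ProM (n = 6) and 88.7% ± 2.2 in Meta (n = 7). The number of arrays limits the precision of every comparison. The 10 brightest probes held 8.5% ± 0.4 of the summed signal in PreM (n = 5), 7.7% ± 0.6 in early ProM (n = 5), 10.2% ± 1.5 in late ProM (n = 6) and 12.0% ± 1.5 in Meta (n = 7). The files used here name contigs and do not pair them with genes, so probes are given by contig, by the coding range that the contig name holds, and by sequence.

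The title of the study asks whether postembryonic development falls into discrete stages. Shares of variance between labelled stages cannot decide this, because a gradual change divided into stages would also give them. Stage accounted for 49.2% of the variance of the whole profiles (permutation test, p = 1e-05, the smallest that 100000 permutations can give). The samples of PreM and Meta lay farthest apart, with 54.8% of their joint variance between the stages (exact permutation test, p = 0.00126, adjusted p = 0.00379 over 6 pairs). The share was 45.8% for early ProM and Meta (exact p = 0.00126, adjusted p = 0.00379) and 42.5% for PreM and late ProM (exact p = 0.00216, adjusted p = 0.00433). Of the consecutive stages, early and late ProM were separated by 30% (exact p = 0.013, adjusted p = 0.0156) and PreM and early ProM by 29.5% (exact p = 0.00794, adjusted p = 0.0119). Late ProM and Meta were the closest, at 18% (exact p = 0.0385, adjusted p = 0.0385). Slide means hold part of the stage difference, since stages were unevenly spread over slides. With slide means removed, the share of late ProM and Meta missed the threshold (14.2%, adjusted p = 0.0641). Over 7 alternatives its adjusted p was 0.035 to 0.0734. The permutation tests have one side by construction. For every pair with PreM, and for early ProM and Meta, the exact p was the smallest that the number of splits allows. Such p-values do not rank the separations. Slides accounted for 14.9% of the variance left after the stage means were removed (permutation test, p = 0.0464).

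The first principal component, with 40.9% of the variance, followed the order of development. Its mean score was −65.6 ± 21.2 in PreM (SD, n = 5), −43.3 ± 15.4 in early ProM (n = 5), 23.7 ± 20.5 in late ProM (n = 6) and 57.4 ± 14.8 in Meta (n = 7). The step of 67.1 from early to late ProM was the widest (two-sided exact permutation test, p = 0.00433, adjusted p = 0.00962 over 3 steps). The step of 33.7 from late ProM to Meta also passed this test (exact p = 0.00641, adjusted p = 0.00962). The step of 22.2 from PreM to early ProM did not (exact p = 0.103, adjusted p = 0.103). The second component, with 20.7% of the variance, spread samples within stages.

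**Figure D1:**
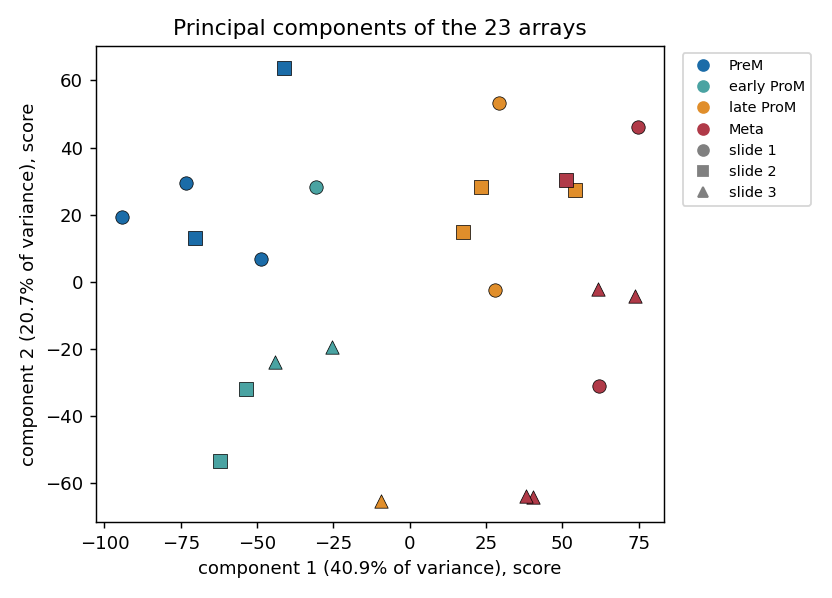
Scores of the 23 arrays on the first (horizontal) and second (vertical) principal component, in score units, with colours for stages and shapes for slides. PreM and early ProM samples lie to the left, between −94.4 and −25.4, and late ProM and Meta samples to the right, between −9.5 and 74.8.

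Across the 4 stages, 6109 of 11635 probes changed (52.5%; moderated F test of limma, adjusted p under 0.05), and 6007 with slide as a block. A total of 227 of these spanned at least 10-fold between their lowest and highest stage means. Of the 227, 108 were highest in Meta and 83 in PreM, with 26 highest in late ProM and 10 in early ProM. Stage means rose without interruption in 91 and fell without interruption in 64. The largest step between consecutive stages was a rise from early to late ProM for 84 probes (37.0%) and a fall at that step for 34 (15%). It was a rise from PreM to early ProM for 41 and a fall for 21. From late ProM to Meta the largest steps were mostly falls, 40 against 7 rises.

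**Figure D2:**
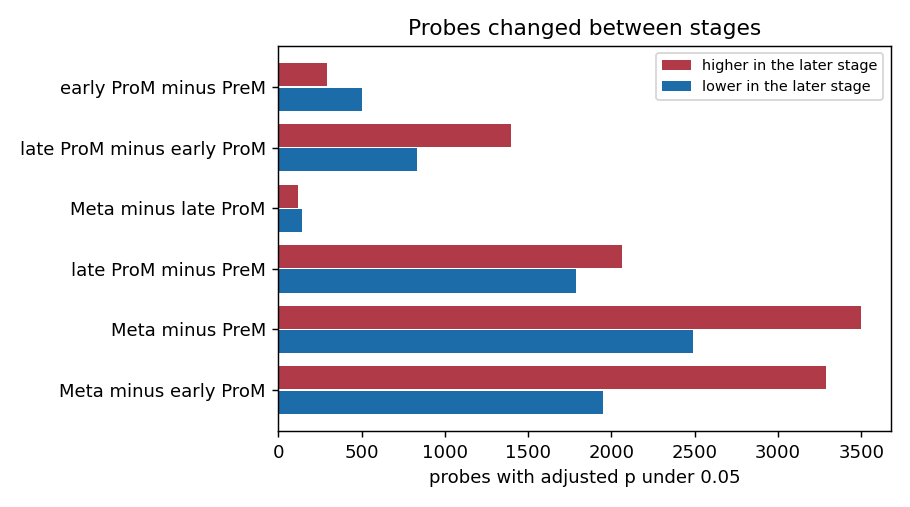
Number of probes with adjusted p under 0.05 (horizontal axis) in each of the 6 comparisons of 2 stages, higher (red bars) or lower (blue bars) in the later stage. With scaling to the 75th percentile, Meta against PreM held the most, 3501 higher and 2487 lower, and Meta against late ProM the fewest, 115 higher and 141 lower.

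The division into higher and lower probes depended on how arrays were scaled. With each array scaled to its 75th percentile, the median log2 difference of all probes was −0.03 from PreM to early ProM, 0.10 from early to late ProM, 0.06 from late ProM to Meta and 0.19 from PreM to Meta. With quantile normalization the same medians were −0.01, −0.03, −0.03 and 0.00. Scaling to the median gave −0.06, −0.06, −0.01 and −0.07, and normexp background correction −0.14, 0.23, 0.12 and 0.26. The differences of the probes named here are larger than these shifts.

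Probes are named below from those past the threshold whose arrays did not overlap between the stages compared. This choice fixes their direction within each slide and without any array, so only the sizes there are informative. From PreM to early ProM, the probe of comp320802_c0_seq1, a contig without a coding range in its name (probe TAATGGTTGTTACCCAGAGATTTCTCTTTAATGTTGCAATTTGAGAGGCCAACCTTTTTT), was up-regulated by 9.47 ± 1.15 on the log2 scale (SE, adjusted p = 4.33e-05). It was well above background on 1 of 5 PreM arrays and on all early ProM arrays, with mean log2 levels of −6.55 ± 3.03 (SD, n = 5) and 2.92 ± 1.80 (n = 5) relative to the 75th percentile. The probe of comp413570_c0_seq3, coding range 534 to 1628 (probe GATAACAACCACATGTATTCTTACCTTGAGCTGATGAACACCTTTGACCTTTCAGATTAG), rose by 7.77 ± 0.92 (SE, adjusted p = 4.33e-05), from −3.36 ± 3.24 (SD, n = 5) to 4.40 ± 0.81 (n = 5), and was well above background on 3 of 5 PreM arrays. In the opposite direction, comp392000_c0_seq1, coding range 2994 to 3296 (probe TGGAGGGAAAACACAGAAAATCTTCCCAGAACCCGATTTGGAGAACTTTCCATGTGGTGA), fell from 0.20 ± 1.59 (SD, n = 5) to −3.85 ± 0.87 (n = 5), a log2 difference of −4.04 ± 0.99 (SE, adjusted p = 0.0154). It did not stay low, and its mean in Meta was 0.31 ± 1.91 (n = 7). The probe of comp120717_c1_seq8, without a coding range (probe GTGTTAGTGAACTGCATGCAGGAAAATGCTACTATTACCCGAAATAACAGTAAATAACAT), fell from −1.99 ± 0.61 (n = 5) to −5.99 ± 2.05 (n = 5), by −4.00 ± 0.71 (SE, adjusted p = 0.00157), and 2 of 5 early ProM arrays were well above background. Normexp correction, whose added offset raises dim signals, gave smaller log2 differences of 6.01 for comp320802_c0_seq1, 6.32 for comp413570_c0_seq3, −3.12 for comp392000_c0_seq1 and −1.80 for comp120717_c1_seq8, so their sizes depend on how signal near background is treated. Single arrays also moved them. The level of comp320802_c0_seq1 was at least 596-fold higher without PreM 5, when no PreM array was well above background, and its log2 difference was 8.87 without early ProM 2. That of comp413570_c0_seq3 was 9.09 without PreM 5, 7.13 without PreM 2 and 7.09 without PreM 4, and that of comp120717_c1_seq8 was −4.73 without early ProM 1. Blocked by slide, these log2 differences were 9.77, 7.59, −3.74 and −3.94. Within slide 2 they were 6.79, 5.84, −3.31 and −4.01, and none passed the threshold there (limma, adjusted p = 0.116, 0.142, 0.175 and 0.0716). Within slide 1, which held 1 early ProM array, comp413570_c0_seq3 and comp392000_c0_seq1 gave 9.45 and −5.08, comp320802_c0_seq1 was at least 3100-fold higher and comp120717_c1_seq8 at least 16.3-fold lower. Slide 3 held no PreM array.

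In all, 797 of 11635 probes passed (limma, adjusted p under 0.05) from PreM to early ProM, 293 higher and 504 lower, and 17 rose and 7 fell by at least 10-fold. With slide as a block 517 passed, of which 484 were among the 797. The slides share no array, and slides 1 and 2 went alike in one reading and not in the other. Of 1793 probes at least 2-fold different on slide 1, 68.7% went the same way on slide 2 (50.9% expected if unrelated), and of 2520 on slide 2, 49.5% did so on slide 1 (51.4% expected). Age differed between these stages, and with day as a covariate 43 probes passed, 25 higher and 18 lower. The rises of comp320802_c0_seq1 and comp413570_c0_seq3 were then 8.91 and 6.83. The falls of comp392000_c0_seq1 (−2.95, adjusted p = 0.312) and comp120717_c1_seq8 (−2.89, adjusted p = 0.138) then missed the threshold. Over the alternatives fitted to all slides their adjusted p ranged from 0.00515 to 0.312 and from 0.000467 to 0.277. The latter also missed it on the authors' values (−2.51, adjusted p = 0.277). The count was 489 without PreM 2 and 435 without early ProM 3. The split was 219 higher and 253 lower on the authors' values and 204 higher and 621 lower after normexp correction.

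The passage from early to late ProM held the most changed probes of the 3 consecutive steps in most settings. The exceptions were the fit with array signal as a covariate (753, against 1298 from late ProM to Meta) and the fits within slide 1 (2 probes) and slide 3 (0 probes in limma, 1120 at an unadjusted p under 0.05). Slide 1 held 1 early ProM array and slide 3 held 1 late ProM array, so the spread there came from the other arrays of the slide. The probe of comp1853662_c0_seq1, coding range 17 to 565 (probe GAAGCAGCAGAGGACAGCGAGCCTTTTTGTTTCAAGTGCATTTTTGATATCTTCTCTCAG), was up-regulated by 5.71 ± 0.80 on the log2 scale (SE, adjusted p = 0.000273), from −0.21 ± 2.57 (SD, n = 5) to 5.50 ± 0.56 (n = 6). It then stayed near that level, at 4.70 ± 0.57 in Meta (n = 7). The probe of comp90855_c0_seq1, without a coding range (probe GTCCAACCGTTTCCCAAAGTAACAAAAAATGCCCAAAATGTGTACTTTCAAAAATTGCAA), rose by 5.65 ± 0.82 (SE, adjusted p = 0.000335), from −1.28 ± 2.31 (n = 5) to 4.36 ± 1.52 (n = 6). Of the falls, the largest by the same rule was that of comp427525_c0_seq1, coding range 22 to 1695 (probe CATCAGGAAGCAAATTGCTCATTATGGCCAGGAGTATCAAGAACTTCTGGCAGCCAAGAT), which fell from 5.18 ± 1.35 (SD, n = 5) to 1.40 ± 1.38 (n = 6), a difference of −3.78 ± 0.60 (SE, adjusted p = 0.000591). The probe of comp418912_c0_seq1, coding range 113 to 1252 (probe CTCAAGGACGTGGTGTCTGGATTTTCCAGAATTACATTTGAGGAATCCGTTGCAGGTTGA), was well above background on 4 of 5 early ProM arrays and on none in late ProM or Meta. Its level in late ProM was at least 3.56-fold lower (adjusted p = 0.0028), a bound set against the dimmest probes well above background on each array. The bound was 5.37-fold without early ProM 3 and 2.58-fold without early ProM 1. This bound holds for signals without normexp correction, which left −0.43 for it (adjusted p = 0.385), and with day as a covariate it missed the threshold too (−1.80, adjusted p = 0.1). Its adjusted p ranged from 0.000685 to 0.385 over the alternatives fitted to all slides. It was lower in the fit blocked by slide (adjusted p = 0.00368), and at least 2.49-fold, 4.28-fold and 5.07-fold lower within slides 1, 2 and 3. For the other probes the log2 differences were 4.59, 4.51 and −2.53 with day as a covariate, and 5.95, 5.57 and −3.84 blocked by slide. They were 5.31, 4.18 and −1.97 within slide 1, 7.47, 7.26 and −5.30 within slide 2, and 4.36, 4.08 and −2.63 within slide 3. Without early ProM 3 the rises were 6.69 and 6.42, and without early ProM 4 that of comp1853662_c0_seq1 was 4.97.

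From early to late ProM 2229 probes passed (limma, adjusted p under 0.05), 1399 higher and 830 lower, and 18 rose and 4 fell by at least 10-fold. The split was 940 higher and 1064 lower with quantile normalization, 937 and 1288 with scaling to the median, and 3418 and 861 with normexp correction. With slide as a block 1854 passed, and 1752 of them were among the 2229. Slides 1 and 2 went alike and slides 2 and 3 did not. Of 1956 probes at least 2-fold different on slide 1, 82.9% went the same way on slide 2 (54.9% expected if unrelated) and 61.1% on slide 3 (49.2% expected). Of 3502 on slide 2, 37.9% did so on slide 3 (49.4% expected), which held 1 late ProM array. Early ProM arrays were on average brighter relative to the added spike-in RNA, and with that measure as a covariate, an alternative added after the data were seen, 753 passed, 328 higher and 425 lower. With day as a covariate 381 passed, 149 higher and 232 lower. The count was 1390 without early ProM 4, 1064 without early ProM 5, 1179 without late ProM 6 and 3651 without late ProM 3.

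From late ProM to Meta, the largest rise among probes whose stages did not overlap was that of comp360582_c1_seq2, coding range 2 to 610 (probe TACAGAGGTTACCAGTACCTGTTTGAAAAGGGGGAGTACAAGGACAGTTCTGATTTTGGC), which was well above background on 5 of 7 Meta arrays and on no late ProM array. It was at least 2.35-fold higher in Meta (adjusted p = 0.0133) without normexp correction, which gave a log2 difference of 0.48 (adjusted p = 0.0395; 0.00379 to 0.0454 over the alternatives fitted to all slides). Within slide 1, which held 2 arrays of each of these stages, it missed the threshold (limma, adjusted p = 0.869). Slide 2 held 1 Meta array and slide 3 held 1 late ProM array. The fits there gave log2 differences of 0.84 and 2.43 for this probe, and only these sizes are given because they rest on 1 array of a stage. The probe of comp105848_c0_seq2, coding range 135 to 677 (probe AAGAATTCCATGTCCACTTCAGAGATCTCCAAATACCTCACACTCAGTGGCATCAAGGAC), rose from −5.69 ± 0.45 (SD, n = 6) to −4.22 ± 0.88 (n = 7), by 1.47 ± 0.32 (SE, adjusted p = 0.0195), and was well above background on 1 of 6 late ProM arrays. The probe of comp425281_c0_seq7, coding range 997 to 3822 (probe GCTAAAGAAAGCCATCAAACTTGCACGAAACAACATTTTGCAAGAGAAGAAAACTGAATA), was well above background on every late ProM array and on no Meta array, and was at least 6.73-fold lower in Meta (adjusted p = 0.00126). The probe of comp419024_c0_seq5, coding range 2612 to 3403 (probe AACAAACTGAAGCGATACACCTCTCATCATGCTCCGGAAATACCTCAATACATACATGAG), fell from 1.07 ± 0.53 (SD, n = 6) to −1.49 ± 1.01 (n = 7), by −2.56 ± 0.36 (SE, adjusted p = 0.000573). Blocked by slide, comp360582_c1_seq2 was higher (adjusted p = 0.0407) and comp425281_c0_seq7 lower (adjusted p = 0.00686). Within slides 1, 2 and 3, comp425281_c0_seq7 was at least 2.32-fold, 6.41-fold and 22-fold lower. In the fit to slide 1 it missed the threshold (limma, adjusted p = 0.532), as did comp105848_c0_seq2 (adjusted p = 0.156), while comp419024_c0_seq5 passed. The rise of comp360582_c1_seq2 was at least 1.81-fold within slide 1 and 5.26-fold within slide 3, and within slide 2 none of its arrays in these stages was well above background. The blocked log2 differences of comp105848_c0_seq2 and comp419024_c0_seq5 were 1.58 and −2.36. The latter gave −3.04, −0.28 and −3.32 within slides 1, 2 and 3. The former was at least 5.6-fold higher within slide 1, at least 1.79-fold higher within slide 2 and 0.54 higher on the log2 scale within slide 3. Some of these calls ended under another processing. After normexp correction comp425281_c0_seq7 gave −0.85 (adjusted p = 0.0862), below its bound, and comp105848_c0_seq2 gave 0.54 (adjusted p = 0.0449). The latter gave 1.24 with quantile normalization (adjusted p = 0.067) and 1.41 without late ProM 2 (adjusted p = 0.0564). Over the alternatives fitted to all slides their adjusted p ranged from 0.000186 to 0.0862 and from 0.00881 to 0.0907.

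The deepest falls into the climax were in probes whose arrays overlapped between the stages, so the rule for named probes left them out of this comparison. They were followed after their values were seen. A total of 15 probes were at least 10-fold lower in Meta than in late ProM, against 1 at least 10-fold higher. Their mean log2 level was 4.25 ± 0.21 in PreM (SD, n = 5), 3.75 ± 0.34 in early ProM (n = 5) and 2.41 ± 0.60 in late ProM (n = 6). It was −3.69 ± 0.48 on 6 Meta arrays and 2.14 on the array of Meta 1. The array of Meta 1 lay at or above the lowest late ProM array in all 15. The widest fall was that of comp404832_c0_seq1, coding range 129 to 809, with mean log2 levels of 7.20 in PreM, 7.38 in early ProM, 7.13 in late ProM and −4.42 on the 6 other Meta arrays, against 7.10 in Meta 1.

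**Figure D3:**
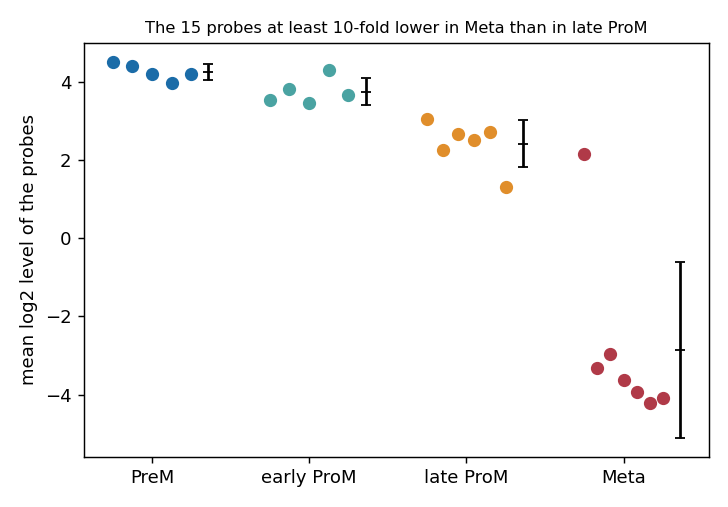
Mean log2 level of the 15 probes that were at least 10-fold lower in Meta than in late ProM, relative to each array's 75th percentile (vertical axis), by stage. Each point is an array and the black marks are the mean ± SD of the stage. Of the Meta arrays 6 lie between −4.22 and −2.97, and Meta 1 lies at 2.14, within the range of late ProM.

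From late ProM to Meta 256 probes passed (limma, adjusted p under 0.05), 115 higher and 141 lower. The split was 90 higher and 245 lower with quantile normalization, 96 and 225 with scaling to the median, and 342 and 199 with normexp correction. With slide as a block 146 passed, and 120 of them were among the 256. Of 1100 probes at least 2-fold different on slide 1, 69.8% went the same way on slide 2 (56.4% expected if unrelated), which held 1 Meta array, and 79.3% on slide 3 (56.0% expected), which held 1 late ProM array. A fit to these 2 stages alone called 28, array weights 1428 (694 higher and 734 lower), and array signal over spike-in as a covariate 1298 (734 higher and 564 lower). The count was 80, 78, 148, 161 and 570 without late ProM 1, 2, 3, 4 and 6, and 404, 120, 121 and 150 without Meta 1, 4, 5 and 6.

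Between the ends of the series, PreM and Meta, the level of comp320802_c0_seq1 reached 7.32 ± 0.58 in Meta (SD, n = 7), 13.88 ± 1.06 above PreM on the log2 scale (SE, adjusted p = 2.7e-09). The probe of comp225436_c0_seq1, coding range 92 to 568 (probe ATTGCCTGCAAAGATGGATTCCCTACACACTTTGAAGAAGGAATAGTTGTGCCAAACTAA), rose by 12.30 ± 0.79 (SE, adjusted p = 5.78e-10). It went from −6.37 ± 0.97 in PreM (SD, n = 5), where 2 of 5 arrays were well above background, through 0.71 ± 2.89 in early ProM (n = 5) to 6.05 ± 0.37 in late ProM (n = 6) and 5.93 ± 0.51 in Meta (n = 7). The probe of comp427197_c0_seq1, coding range 138 to 7478 (probe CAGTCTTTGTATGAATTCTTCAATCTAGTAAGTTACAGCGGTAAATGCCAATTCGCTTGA), fell from 2.27 ± 0.20 (n = 5) to −6.63 ± 2.60 (n = 7), by −8.90 ± 0.87 (SE, adjusted p = 6.33e-08). The probe of comp228123_c0_seq1, coding range 2388 to 2840 (probe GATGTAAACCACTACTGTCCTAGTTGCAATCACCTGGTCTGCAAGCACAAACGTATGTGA), fell from 3.43 ± 0.67 (n = 5) to −5.16 ± 3.12 (n = 7), by −8.59 ± 1.01 (SE, adjusted p = 6.27e-07). Both were well above background on 1 of 7 Meta arrays, that of Meta 1. All 4 differences rest on a stage mostly near background, and normexp correction gave 10.33, 9.17, −5.11 and −5.73. With day as a covariate they were 12.97, 10.26, −8.07 and −7.58. Without PreM 5, comp320802_c0_seq1 was at least 12600-fold higher, and without Meta 1 the falls were at least 315-fold and 701-fold, no array of the dim stage then being well above background. In the fit blocked by slide the 4 differences were 14.49, 12.00, −8.32 and −7.70. Within slide 2, where Meta 1 was the Meta array, they were 12.05, 12.03, −3.05 and −1.71. Within slide 1 the rises were at least 11700-fold and 3660-fold and the falls at least 258-fold and 520-fold.

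**Figure D4:**
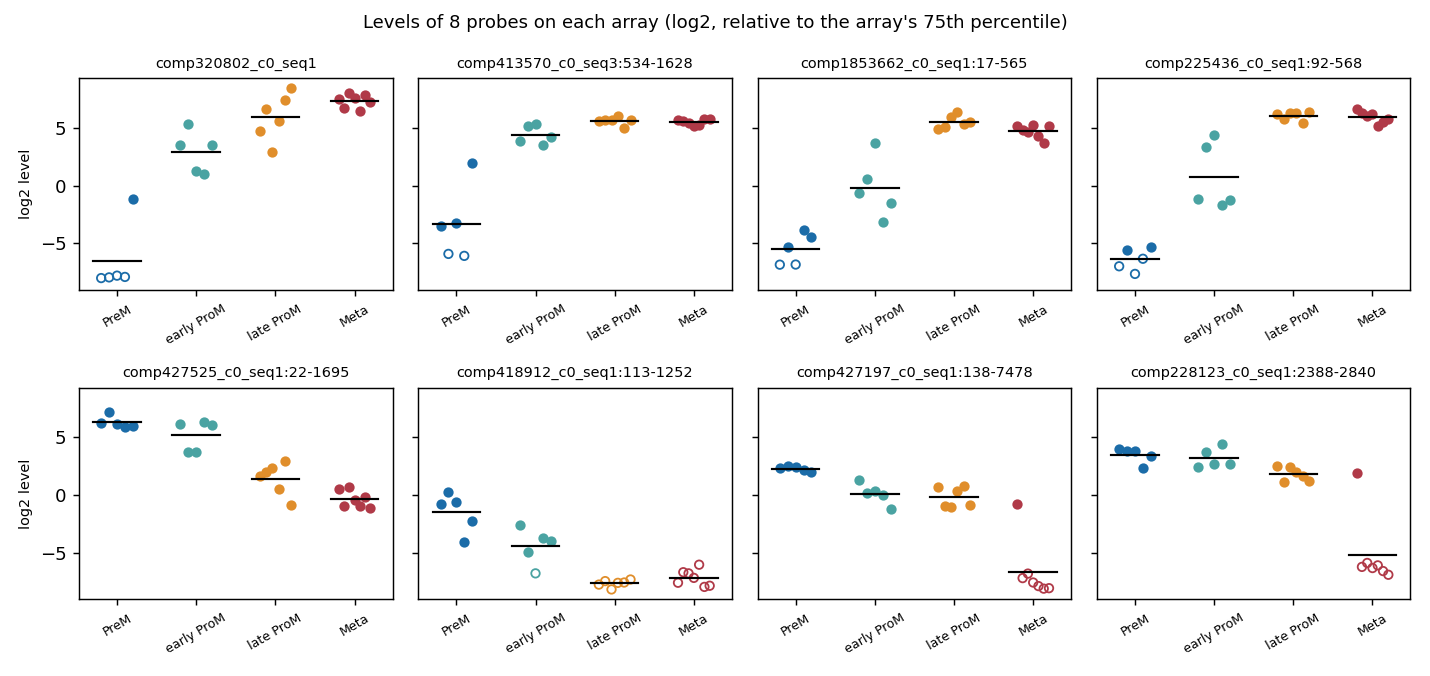
Log2 level of 8 probes on each of the 23 arrays, relative to the array's 75th percentile (vertical axes), by stage. Filled points are well above background, open points are not, and black lines are stage means. The level of comp225436_c0_seq1 goes from −6.37 in PreM to 6.05 in late ProM, and that of comp228123_c0_seq1 falls to −5.16 in Meta while the array of Meta 1 stays near late ProM.

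In all, 5988 probes passed between PreM and Meta (51.5%; limma, adjusted p under 0.05), 3501 higher and 2487 lower, with 118 at least 10-fold higher and 79 at least 10-fold lower. The split was 2423 higher and 3090 lower with quantile normalization, and 2397 and 3494 with scaling to the median. It was 4411 and 2070 with normexp correction and 3224 and 2474 on the authors' values. With slide as a block 5565 passed, and 5056 of them were among the 5988. Of 4061 probes at least 2-fold different on slide 1, 95% went the same way on slide 2 (55.9% expected if unrelated), which held 1 Meta array. With day as a covariate 2128 passed, 1005 higher and 1123 lower.

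The other pairs set stages further apart side by side. Between PreM and late ProM 3846 probes passed (limma, adjusted p under 0.05), 2061 higher and 1785 lower, and 3988 with slide as a block. The rises of comp320802_c0_seq1 and comp225436_c0_seq1 were 12.50 ± 1.10 (SE, adjusted p = 5.62e-08) and 12.41 ± 0.82 (adjusted p = 1.88e-09) against PreM levels mostly near background, and 8.98 and 9.31 with normexp correction. Without PreM 5, comp320802_c0_seq1 was at least 4880-fold higher, and its log2 difference was 13.11 without late ProM 3. The level of comp418912_c0_seq1 was at least 26.9-fold lower in late ProM (adjusted p = 5.57e-07) without normexp correction, which gave a smaller log2 difference of −2.33 (adjusted p = 7.73e-05). The bound was 41.9-fold without PreM 4 and 19.8-fold without PreM 2. The probe of comp89552_c0_seq2, coding range 243 to 1304 (probe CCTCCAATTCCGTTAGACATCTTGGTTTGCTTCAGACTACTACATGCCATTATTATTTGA), fell by −5.26 ± 0.32 (SE, adjusted p = 1.08e-09), from 3.59 ± 0.50 (SD, n = 5) to −1.67 ± 0.33 (n = 6). In the fit blocked by slide comp418912_c0_seq1 was lower (adjusted p = 2.22e-06), and it was at least 21.5-fold and 31.3-fold lower within slides 1 and 2. The other blocked differences were 12.56, 12.36 and −5.15. They were 11.14, 11.56 and −4.93 within slide 2. Within slide 1 the rises were at least 6950-fold and 4430-fold, and the fall was −5.18. Of 2779 probes at least 2-fold different on slide 1, 95.6% went the same way on slide 2 (53.1% expected if unrelated). The split was 1612 higher and 2077 lower with quantile normalization and 1423 and 2497 with scaling to the median. It was 1703 and 1458 with normexp correction and 1844 and 1632 on the authors' values. With day as a covariate 330 passed, 142 higher and 188 lower. The other 3 probes then gave 11.46, 10.07 and −4.00, and comp418912_c0_seq1 missed the threshold (−3.08, adjusted p = 0.0634; 2.56e-07 to 0.0634 over the alternatives fitted to all slides).

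Between early ProM and Meta 5237 probes passed (limma, adjusted p under 0.05), 3286 higher and 1951 lower. The count was 5523 with slide as a block and 2588 with slide and array signal over spike-in together in the fit, an alternative added after the data were seen. The probe of comp90855_c0_seq1 rose by 7.0 ± 0.80 (SE, adjusted p = 1.57e-06) to 5.72 ± 0.81 in Meta (SD, n = 7). The probe of comp115675_c0_seq5, coding range 376 to 1863 (probe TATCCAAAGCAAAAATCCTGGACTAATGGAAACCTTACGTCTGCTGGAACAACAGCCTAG), was higher in Meta (adjusted p = 2.92e-08). It was well above background on 1 of 5 early ProM arrays, so the fitted log2 difference of 5.83 depends on the level of background. The levels of comp228123_c0_seq1 and of comp415733_c0_seq3, coding range 517 to 1536 (probe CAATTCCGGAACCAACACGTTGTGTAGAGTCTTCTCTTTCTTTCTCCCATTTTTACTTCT), fell by −8.34 ± 1.01 (SE, adjusted p = 3.13e-06) and −8.06 ± 0.93 (adjusted p = 1.79e-06), with 1 and 3 of 7 Meta arrays well above background. Normexp correction gave 6.59, 2.85, −5.51 and −5.66 for these 4 probes. The rise of comp90855_c0_seq1 was 7.78 without early ProM 3, and without Meta 1 comp228123_c0_seq1 was at least 589-fold lower and comp415733_c0_seq3 fell by −9.09. In the fit blocked by slide the 4 differences were 6.85, 5.84, −7.87 and −7.66. Within slides 1, 2 and 3, comp90855_c0_seq1 gave 5.81, 8.58 and 6.04. The rise of comp115675_c0_seq5 was at least 34.6-fold within slide 1 and 74.1-fold within slide 2, and 5.35 on the log2 scale within slide 3. Within slide 2, where Meta 1 was the Meta array, the falls were −1.68 and −2.59. They were at least 672-fold and 604-fold within slide 1, and at least 427-fold and −7.98 on the log2 scale within slide 3. Of 4007 probes at least 2-fold different on slide 1, 79.1% went the same way on slide 2 (54.7% expected if unrelated) and 91.6% on slide 3 (57.5% expected). The split was 2165 higher and 2611 lower with quantile normalization, 2273 and 2844 with scaling to the median, and 5520 and 1670 with normexp correction.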

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

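All tests of the second component and of Meta 1, and the fit with array signal as a covariate, were chosen after the result was seen. Those of age and the regroupings of arrays were not. An array was singled out where its gap to the nearest array of its stage took up more of the stage's range than Dixon's 95% limit allows. This was asked of 40 stage-wise sets of array measures and 72 of named probes, and 3 and 6 exceeded it. Chance does so in about 1 set in 20.

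The 3 probes of comp427197_c0_seq1, comp228123_c0_seq1 and comp415733_c0_seq3 stood at −0.82, 1.87 and 1.43 on the array of Meta 1, and at no more than −6.80, −5.88 and −5.00 on the other Meta arrays. In the 15 probes at least 10-fold lower in Meta than in late ProM, Meta 1 averaged 2.14, the other 6 Meta arrays −3.69 ± 0.48 (SD) and late ProM 2.41 ± 0.60 (SD, n = 6). Late ProM arrays of slide 2 lay 0.43 below those of slides 1 and 3 (a log2 difference of −0.43), −7.3% of the excess of Meta 1. PreM and early ProM arrays of slide 2 lay 0.23 above those of the other slides, against an excess of 5.83 in Meta 1. Both values argue against a shift of all signals on slide 2. These probes were bright in those stages, so a slide effect on dim signals alone was not tested. Over all tested probes Meta 1 lay closer to the late ProM mean than to the mean of the other Meta arrays, with a margin of −0.12 in log2 distance, against −0.01 to 0.27 for the other 6. Slide 2 held 3 of the 6 late ProM arrays and no other Meta array, so slide is mixed into this distance. On the first component Meta 1 scored 51.2, within the range of Meta (37.9 to 74.8, mean 57.4) and of late ProM (−9.5 to 54.0, mean 23.7). A wrong stage label may explain the late ProM levels in Meta 1, as may a larva at the start of the climax, which was not tested apart.

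The second component, which spread samples within stages, went with array signal over spike-in signal. Within stages Pearson's r was −0.83 and Spearman's rho −0.79 (permutation p = 1e-05, the smallest 100000 permutations can give, and 6e-05), r was −0.77 without the 2 farthest arrays, and −0.72, −0.76 and −0.96 within slides 1, 2 and 3. The variance between arrays of one stage and one slide was 64.0% of that within stages, each per degree of freedom. This ratio is not the share of the spread that slides leave. It argues against slide as the whole cause, and slide may still hold a large part of the spread. Age is argued against by r = 0.07 (95% bootstrap interval −0.22 to 0.40). The amount or labelling of RNA may drive this component, and so might the makeup of the clipped tissue, for which no test was run.

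From PreM to early ProM, 797 calls became 43 with day as a covariate. The 797 probes kept a median of 81.5% of their log2 difference (quartiles 70.9% and 94.6%; median size 1.18 before and 0.99 after) and 100% kept its sign, while standard errors grew 1.25-fold, under the 1.3-fold set in advance. An effect of age itself was tested on other arrays: 68.0% of the probes had a slope on day within late ProM and Meta that went with their difference, a share that 16 of 100 orders of the days reached. It was 71.9% within Meta and 49.6% within late ProM. All 43 probes that passed with day in the fit were among the 797, including comp320802_c0_seq1 (8.91) and comp413570_c0_seq3 (6.83). Their differences went beyond a linear effect of day, the only course of age fitted. For the other probes age and stage cannot be told apart, because age rose with stage and few arrays overlapped in age.

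Among the array measures, Meta 3 had a spike-in signal of 14.61 (log2; other Meta arrays 13.39 to 13.87) and 84.01% of probes well above background (others 88.30% to 90.25%). The 10 brightest probes held 7.88% of the signal in PreM 4 and 8.59% to 8.76% in other PreM arrays. The level of comp320802_c0_seq1 was −1.14 in PreM 5 and at most −7.79 in other PreM arrays. The level of comp427525_c0_seq1 was 7.14 in PreM 2 and at most 6.20 in the others. That of comp115675_c0_seq5 was −5.31 in PreM 1 and at most −6.65 in the others.

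For every count of changed probes, under 5% of 100 groupings of the arrays, the real one included, reached the real count. The groupings were not kept within slides, and the counts were not adjusted for one another. Shares of 2 or 3 in 100 are too imprecise to exclude chance for late ProM to Meta and for early to late ProM. Across the 4 stages 1 of 100 groupings, the real one, reached 6109, and the highest other gave 970. For PreM to early ProM it was 1 of 100 (797; highest other 644), for PreM to late ProM 1 (3846; 2640), for PreM to Meta 1 (5988; 3830) and for early ProM to Meta 1 (5237; 3017). For late ProM to Meta 2 of 100 reached 256, the highest other giving 281. For early to late ProM 3 of 100 reached 2229, and the highest other gave 2915. In that split 5 arrays, 4 of them late ProM, averaged −4.51 in signal over spike-in (log2; −4.93 to −4.08) and the other 6 averaged −3.53 (−4.29 to −2.65). All arrays of slide 3 lay among the other 6, so signal, slide and stage are mixed in it. The real split gave 1854 with slide as a block, 753 with that signal as a covariate and 802 with both.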

How the results depend on the processing

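The array signal covariate, its combination with the slide block and averaging by probe name were chosen after the data were seen. Apart from leaving out arrays, 89 of 135 recomputed counts stayed within 1.5 times the value reported, 46 of 49 shares of variance kept their side of the threshold and 300 of 337 log2 differences of named probes did. No log2 difference of a named probe changed sign. Within single slides and without single arrays none could, because named probes were chosen for stages that did not overlap. The balance of higher and lower probes turned with the scaling in several pairs (early to late ProM 1399 and 830, but 940 and 1064 with quantile normalization). Leaving out each array kept 146 of 161 counts, 155 of 161 shares and 551 of 552 log2 differences. The cause was not tested unless stated. Counts below are for PreM to early ProM, early to late ProM, late ProM to Meta, PreM to late ProM, PreM to Meta and early ProM to Meta. A 2-fold threshold keeps fewer probes by construction and left 508, 1056, 145, 1908, 3208 and 2587, and 3806 across the stages. A threshold of 0.01 left 300, 707, 50 and 2330 for the pairs up to PreM and late ProM. Fewer arrays within slide 1 left 35, 2, 30, 883, 2375 and 236, and 1105 across the stages. Within slide 2 the counts were 70 for PreM to early ProM, 0 for late ProM to Meta (limma; 210 at an unadjusted p under 0.05), 952, 158 and 1361 for the last 3 pairs, and 1953 across the stages. Within slide 3 they were 0 for early to late ProM (limma; 1120 unadjusted), 53 for late ProM to Meta and 1266 for early ProM to Meta. Day as a covariate gave 43, 381, 330 and 2128 for PreM to early ProM, early to late ProM, PreM to late ProM and PreM to Meta, and 3039 across the stages. For PreM to early ProM, a slide block gave 517, the 2 stages alone 520, the authors' values 472 and array weights 1342. For late ProM to Meta, a slide block gave 146, the 2 stages alone 28, normexp correction 541, array weights 1428 and the signal covariate 1298. For early to late ProM, normexp correction gave 4279, array weights 4446, the signal covariate 753 and that with a slide block 802. The last setting gave 2588 for early ProM to Meta. The share between late ProM and Meta was 17.2% (adjusted p = 0.053) for probes well above background on all arrays, 15.5% (0.0734) on the authors' values and 14.2% (0.0641) with slide means removed.

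Without one array, PreM to early ProM ranged from 435 to 968, early to late ProM from 1064 to 3651 and late ProM to Meta from 78 to 570. The share between late ProM and Meta ranged from 16.6% to 21.6% (exact permutation tests, adjusted p from 0.0215 to 0.0844). It missed the threshold without late ProM 1 (16.6%), 2 (16.7%) or 4 (17.5%), or Meta 2 (18.2%), 4 (16.9%) or 5 (16.6%). No paired analysis was possible because replicate numbers only name samples. The alternatives for gene lists and for other probes of a named gene were not run, since contigs are not paired with genes in the files used here. Within slide 3 the test across 4 stages was not run, as that slide held no PreM array. Signal over background limits the dim side: folds against a stage without signal are bounds, and normexp correction shrinks them.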

Other observations

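The tests of stage assignment and of age within Meta were chosen after the result was seen. Those of contig classes and of assembly components were set before.

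Samples were mostly closest to their own stage. Of the 23 arrays 18 were nearest to the mean of their own stage, taken without them (permutation p = 2e-05; 5.5 on average over 100000 permutations). Like the shares of variance, this count cannot tell discrete stages from gradual change. The 5 PreM arrays were all nearest to PreM. Of the Meta arrays 5 were nearest to Meta and 2 to late ProM, and of the late ProM arrays 4 were nearest to late ProM, 1 to early ProM and 1 to Meta. Of the early ProM arrays 4 were nearest to their own stage and 1 to late ProM. All 5 exceptions lay nearest to a neighbouring stage, and none of the arrays past PreM was nearest to PreM.

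Contigs without a coding range in their names, a class that can hold untranslated ends and noncoding transcripts, were dimmer on average (mean log2 level −2.31 against −1.56) and changed about as often as the rest. Across the 4 stages 1068 of 1980 changed (53.9%), against 5041 of 9655 with a range (52.2%), a difference of 1.7 percentage points (Fisher's exact test, two-sided p = 0.167). Matched on mean signal in 10 bins the difference was 1.7 points. Of the 227 probes that spanned 10-fold, 44 had no range.

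Probes of one component of the assembly tended to move together. Among 61 pairs of probes of one component that both changed between PreM and Meta, 80.3% moved the same way, against 51.4% for pairs drawn at random (permutation p = 1e-04, the smallest that 10000 permutations can give). In 12 pairs the 2 probes moved in opposite directions, and in 2 of these both did so by at least 2-fold. In comp423280_c0 one probe rose by 2.38 on the log2 scale (limma, adjusted p = 0.000898) and the other gave −2.01 (adjusted p = 0.00811). In comp440120_c0 the values were 2.30 (adjusted p = 0.000245) and −1.18 (adjusted p = 8.46e-06). Both probes of each of these pairs lie on the same contig. These pairs were chosen after their values were seen, and no explanation was tested.

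Within Meta, the first component and age gave Pearson's r = −0.66 (exact permutation p = 0.113, adjusted p = 0.227 over 2 stages, n = 7) and Spearman's rho = −0.71 (exact p = 0.0881). Without the 2 arrays farthest in age r was −0.90 or −0.94, depending on which of 2 arrays tied for second was left out. It was −0.59 within slide 3, and slides 1 and 2 held too few Meta arrays. Within late ProM r was 0.22 (exact p = 0.65, adjusted p = 0.65, n = 6) and rho 0.26 (exact p = 0.667), and r was 0.86 or 0.38 without the 2 arrays farthest in age, again with a tie, and 0.37 within slide 2. That younger Meta animals lie further along the first component stays an open hypothesis, since −0.66 did not pass.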
